A study of Mus musculus with 8 samples.

How the data were processed

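Macrophages were grown from bone marrow of C57BL/6 mice and kept for 24 h with IL4, with LPS plus IFNg, or without stimulus, per the labels' protocols. Per the same protocols, polyadenylated RNA was captured on oligo-dT beads, cDNA was primed with barcoded oligo-dT, samples were pooled by their Actb level in qPCR, and strand-specific 3' end libraries were amplified by PCR. No molecular identifiers are described, so copies made by PCR cannot be told from separate molecules. The submitters' processing notes name TopHat and the mouse build mm9; a version of the aligner, the counting tool and the treatment of reads with several matches are not given in the sources used here. If such reads were dropped, genes with many processed pseudogenes, as ribosomal protein genes and Gapdh have, would be listed too low.

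The authors deposited 1 table of log2 expression values, quantile normalised per its name, with 20259 RefSeq transcript rows and 8 columns. Columns were matched to samples by the barcode in the labels, and the table's own group line gave the same groups. All 8 columns were used. 1 row had no gene symbol and was left out; its values equalled those of Spp1 in every library. The other 20258 rows carried a symbol. RefSeq accessions of 19944 rows matched the GRCm38 gene table, which was used for names and, with GENCODE M21 transcripts, for lengths; no coordinates are given, since the table rests on another build. Between 8219 and 10210 genes per library were listed at exactly 0, and 74 to 202 lay below 0. The treatment of zero counts is not given in the sources used here; if they were left at 0 beside logs of fractional values, a gene without reads ranks above a measured one under 0. Quantile normalisation is meant to give libraries the same distribution, though the numbers of zeros differ here, so it can hide an overall difference in RNA amount, and depth cannot be read from totals per library.

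Genes with 1 same value in every library (6643, of which Prdx1 is the one not at 0, since it was the highest gene in all libraries at 17.3002) were left out, and 13615 were tested. limma 3.58.1 in R 4.3.3 was fitted to all 8 libraries with a mean per group (5 residual degrees of freedom), with an intensity trend in the prior variance (2.31 prior degrees of freedom), so that the groups share an estimate of the spread. Tests were two-sided, adjusted p-values follow Benjamini and Hochberg over the genes tested in a comparison, and a gene passed at an adjusted p of 0.05. Where every library of a group was listed at 0, values are given and no fold.

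29 gene lists written before the data were examined were tested with limma's camera, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 29 lists. They cover alternative activation, inflammatory, interferon, MHC class I and II, glycolysis, pentose phosphate, TCA cycle, oxidative phosphorylation, fatty acid, glutamine, N-glycosylation, arginine, HIF-1, cholesterol, LXR, NRF2, cell cycle, lysosome, ribosomal protein, macrophage identity and immediate early genes, and markers of dendritic cells, neutrophils, mast cells, lymphocytes, erythroid cells, fibroblasts and osteoclasts. The rule for named genes was also fixed beforehand. It takes the 8 largest rises and falls past the threshold with libraries that did not overlap, up to 3 members past the threshold and 1 not past it from each list described, and a fixed set of marker and metabolic genes. Not every gene it takes is described, and 1 gene of the fixed set is not reported here.

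The fits were tested on simulated data with the real genes' means and spreads and 200 changed genes per comparison. For IL4 against no stimulus, 2.99% of genes with a log2 change of 1 were called, 25.4% at 2 and 59.1% at 4, and 3 of 13375 unchanged genes. For LPS plus IFNg against no stimulus these were 0%, 23.9%, 53.0% and 2 genes, and for LPS plus IFNg against IL4 1.49%, 26.9%, 63.6% and 3 genes. In these simulations changes of about 2-fold were mostly missed, as were most genes with a log2 change of 2. Many more genes passed in the real LPS plus IFNg comparisons, which loosens the adjusted threshold, so the shares may be too low for these.

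Alternatives fixed beforehand were no intensity trend, only the 2 groups compared in the fit, the lowest 0.25 of genes by mean left out, low values damped by adding 1 on the linear scale, equal means of 11 housekeeping genes, equal means of the ribosomal protein genes, an added log2 change of 1, an adjusted p of 0.01, array weights, the replicate number as a block, and each library left out. A filter at a mean of 5, setting values below 0 to 0, and fits with 1 control library for each stimulus were added after the data were examined.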

Results

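Gene expression was measured in mouse bone-marrow derived macrophages, immune cells grown from marrow precursors of C57BL/6 mice, after 24 h with no stimulus, with the cytokine IL4, or with bacterial lipopolysaccharide together with interferon gamma (LPS plus IFNg). IL4 is the usual stimulus for alternative activation and LPS plus IFNg for classical activation. The set held 2 unstimulated, 3 IL4 and 3 LPS plus IFNg libraries of 3' end sequencing, which reads only the end of each polyadenylated transcript. Values are the authors' quantile-normalised log2 expression, so a difference of 1 stands for a doubling. Depth is not given with such values. Among the tested genes, 1577 and 2588 were listed at 0 in the unstimulated libraries and 2964 to 3568 in the stimulated ones. More zeros in every stimulated library may mean a lower depth, which comparisons with no stimulus cannot tell apart from the stimulus. How zero counts were treated is not given in the sources used here, so a gene listed at 0 may rank above a measured low one, and the size of changes from means near 0 is uncertain. Between 9967 genes (IL4 replicate 2) and 11837 genes (unstimulated replicate 1) stood above 0 in a library. Across the 7283 genes with a mean of at least 5, Pearson's r across genes was 0.838 to 0.928 between libraries of a group and 0.619 to 0.654 between IL4 and LPS plus IFNg libraries; genes are not independent replicates. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. RefSeq gene symbols are as in the deposited table.

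The comparison of IL4 with no stimulus asks which transcripts alternative activation changes. Genes of the IL-4 response list were higher, among them Arg1, the arginase that turns arginine into ornithine, at 13.58 ± 0.15 (SD, n = 3) against 3.25 ± 1.33 (n = 2). Its log2 change was 10.33 (SE 0.48, adjusted p = 0.000335). Retnla, a secreted resistin-like protein, was at 11.80 ± 0.53 (n = 3) against 0.03 ± 0.05 (n = 2), adjusted p = 0.000656. Mgl2, a lectin, was listed at 0 in both unstimulated libraries and had a mean of 10.37 with IL4. Of 31 measured members, 12 rose, none fell and 19 did not pass, and 22 rose when adjusted over the list alone (camera adjusted p = 2.76e-27, and 0.00156 with an estimated correlation). Flt1 did not pass (log2 change 7.06, adjusted p = 0.0725), and Mrc1, the mannose receptor, went from 10.71 ± 0.43 (n = 2) to 12.07 ± 0.43 (n = 3) with adjusted p = 0.109. Cish and Ch25h were among the 8 largest rises, at 8.94 ± 0.72 and 7.91 ± 0.98 (n = 3) with IL4, and Ch25h was listed at 0 without stimulus. Scn3a, Tmem26 and Il31ra completed those rises.

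Interferon response genes were lower with IL4: 10 of 42 fell, 1 rose and 31 did not pass (20 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.54e-15, and 0.0292 with an estimated correlation). Ifit3 was at 7.40 ± 0.18 (n = 2) without stimulus and listed at 0 in all 3 IL4 libraries. Oas2 fell by 5.73 on the log2 scale (SE 0.64, adjusted p = 0.0134). The riser was Socs1, a negative regulator of cytokine signalling that IL4 also induces, with a log2 change of 5.84 (SE 0.30, adjusted p = 0.000488). Genes of macrophage identity were lower in 6 of 21 cases, with 15 not past the threshold (3 fell with housekeeping scaling, with a median of -0.53 in place of -0.76, and 11 fell adjusted over the list alone; camera adjusted p = 7.53e-09, and 0.0292 with an estimated correlation). Among them Fcgr1, Cx3cr1 and Cd14 had log2 changes of -3.48, -3.17 and -2.87. MHC class II genes were higher as a list (camera adjusted p = 1.86e-05, and 0.0292 with an estimated correlation) with 1 of 9 past the threshold, H2-DMa, at 6.38 ± 0.16 (n = 3) against 3.38 ± 0.04 (n = 2), adjusted p = 0.0266. H2-Eb1 had a log2 change of 2.26 and adjusted p = 0.074. Oxidative phosphorylation genes were higher as a list, by a median of 0.39 over 72 genes, with none past the threshold singly (camera adjusted p = 4.23e-05, and 0.0292 with an estimated correlation).

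Of the arginine, citrulline and polyamine genes, 2 of 16 rose with IL4, Arg1 and the arginine transporter Slc7a2, which had a log2 change of 5.42 (SE 0.21, adjusted p = 0.000262). That list's call (camera adjusted p = 0.00194) was lost with an estimated correlation (adjusted p = 0.203) and without unstimulated replicate 1 (adjusted p = 0.0753). The same held with an estimated correlation for immediate early genes (adjusted p = 0.0967), lysosome genes (adjusted p = 0.226) and neutrophil precursor markers (adjusted p = 0.226), of which 1 of 18 rose, 1 of 41 fell and 0 of 12 passed in limma. Without unstimulated replicate 1 their adjusted p-values were 0.236, 0.201 and 0.0835, and without IL4 replicate 3 those of the lysosome and neutrophil lists were 0.0834 and 0.158. The lysosome list also did not pass with housekeeping scaling (0.0666). Hexokinase Hk2 had a log2 change of 1.55 (adjusted p = 0.0328) and was the only one of 25 glycolysis genes past the threshold. Gapdh, in that list, had means of only 1.14 without stimulus and 3.93 with IL4; it has many processed pseudogenes, and reads matching several places may have been dropped, so its level may be too low. Of the genes of UDP-GlcNAc synthesis, the nucleotide sugar used for protein glycosylation, Gfpt1 had a log2 change of 1.42 (limma adjusted p = 0.0651) and Pgm3 of 2.68 (adjusted p = 0.182). In the wider list, which also holds N-glycosylation genes, 1 of 39 members fell, Gnpda1, and none with housekeeping scaling. The list tests of the glycolysis, pentose phosphate, TCA cycle, fatty acid oxidation, glutamine uptake, N-glycosylation, HIF-1, cholesterol, LXR, NRF2, cell cycle, ribosomal protein, inflammatory, MHC class I, dendritic, mast cell, lymphocyte, erythroid, fibroblast and osteoclast lists did not pass (adjusted p from 0.0593 for HIF-1 targets to 0.892 for inflammatory genes). Some passed under alternatives: HIF-1 targets in 4 (0.0374 to 0.0481), osteoclast markers in 3 (0.0401 to 0.0451), fibroblast markers in 2 (0.0152 and 0.0284) and dendritic markers in 1 (0.0387). Of these lists, the inflammatory had 2 members higher and 2 lower and the LXR list 1 lower, Apoe, at a log2 change of -2.12. The glycolysis list had a median of -0.07 and a mean of 0.08.

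**Figure D1:**
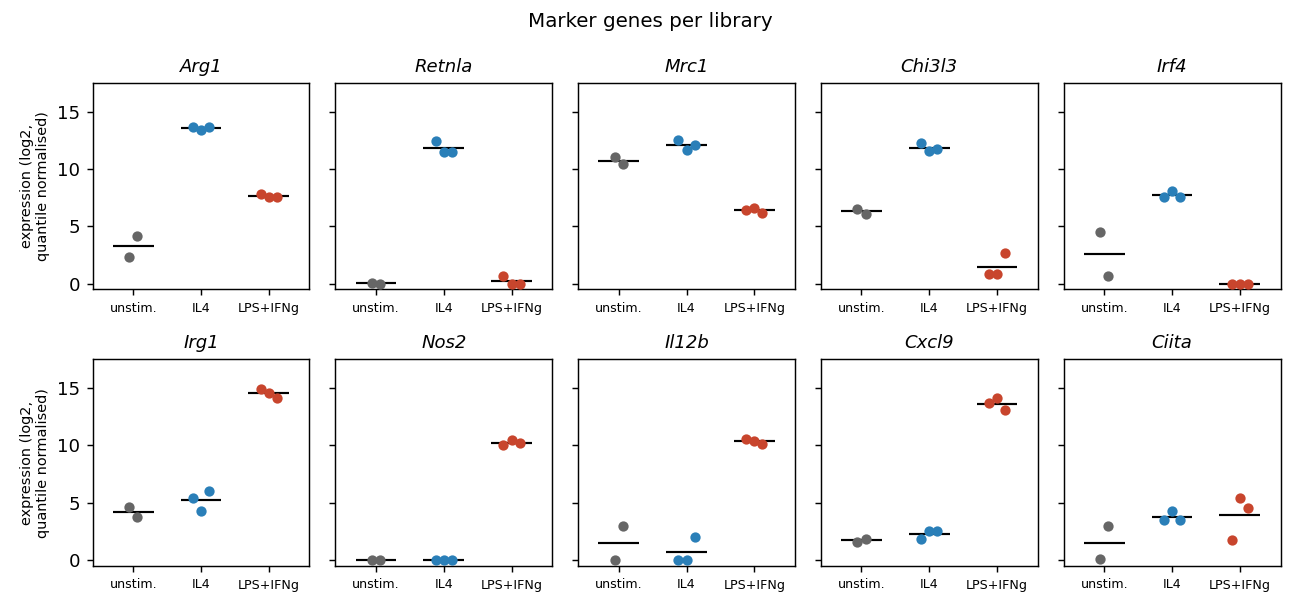
Quantile-normalised log2 expression (vertical axis) of 10 marker genes in each library of the 3 groups (horizontal axis); points are libraries and bars are group means. Arg1 averages 13.58 with IL4 and 7.65 with LPS plus IFNg, and Nos2 is listed at 0 in every library outside the LPS plus IFNg group.

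In limma, 70 genes were higher and 108 lower with IL4 among 13615 tested, or 16 and 54 with only the 2 groups in the fit and 7 and 1 with the replicate number as a block. Libraries of the groups did not overlap in 26.5% of all tested genes, against 20% by chance, and in all 178 called, as a low p nearly requires. The counts moved with the libraries used: 135 and 277 without unstimulated replicate 1, 130 and 177 without unstimulated replicate 2, 45 and 63 without LPS plus IFNg replicate 2, and 40 and 65 without LPS plus IFNg replicate 3. Equal housekeeping means gave 107 higher and 71 lower, a share of 60.1% higher in place of 39.3%, and shifted the median of all genes by 0.23. Of the 30 called genes that the naming rule takes here, 15 stayed past the threshold whichever library was left out. Scn3a did not without unstimulated replicate 2 (adjusted p = 0.0522), nor H2-DMa without IL4 replicate 1 or 2 (up to 0.0615), nor Gnpda1 without any 1 IL4 library or LPS plus IFNg replicate 2 (up to 0.0579). Tmem26, Il31ra, Hk2, Fcgr1, Cx3cr1 and Cd14 did not without either unstimulated library, nor without 4 or more of the others in turn, with adjusted p up to 0.125, 0.109, 0.107, 0.199, 0.107 and 0.122.

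The comparison of LPS plus IFNg with no stimulus asks the same of classical activation. Interferon response genes rose in 34 of 42 cases, none fell, and 38 rose when adjusted over the list alone (camera adjusted p = 2.46e-41, and 0.00762 with an estimated correlation). The chemokine Cxcl9 was at 13.64 ± 0.54 (n = 3) against 1.71 ± 0.21 (n = 2), a log2 change of 11.93 (SE 0.43, adjusted p = 7.38e-05), and Cxcl10 had a log2 change of 8.12 (SE 0.52). Tgtp1, an interferon-inducible GTPase, had a log2 change of 9.65; its row held the same values as that of Tgtp2, so reads of these copies cannot be assigned to either. Of 35 inflammatory and classical activation genes, 20 rose and 1 fell (24 and 1 adjusted over the list alone; camera adjusted p = 1.04e-20, and 0.0111 with an estimated correlation). Nos2, inducible nitric oxide synthase, had a mean of 10.22 and was listed at 0 in both unstimulated libraries. Ptgs2 and Il12b had log2 changes of 9.21 and 8.89, and Cd86 did not pass (5.42, adjusted p = 0.0866). MHC class I genes rose in 12 of 20 cases (17 adjusted over the list alone; camera adjusted p = 1.32e-16, and 0.0103 with an estimated correlation), among them Tapbpl with a log2 change of 4.08, and MHC class II genes in 3 of 9 (adjusted p = 0.000503, and 0.0307 with an estimated correlation). Of the class II genes that rose, H2-Ab1 and H2-Eb1 did not pass without LPS plus IFNg replicate 1 or 3. H2-Q7 and H2-T22 share their values with H2-Q9 and H2-T9.

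Irg1, the enzyme that makes itaconate from the TCA cycle intermediate cis-aconitate, was at 14.55 ± 0.44 (n = 3) with LPS plus IFNg against 4.18 ± 0.59 (n = 2), a log2 change of 10.37 (SE 0.54, adjusted p = 0.000332). Idh1, cytosolic isocitrate dehydrogenase, went from 11.39 ± 0.05 to 8.45 ± 0.35, a log2 change of -2.94 (SE 0.32, adjusted p = 0.00273), and Suclg2 fell by 3.02 (adjusted p = 0.00243). These were the 2 falls in the TCA cycle list of 25 genes, which also holds cytosolic enzymes such as Idh1, and 23 did not pass (camera adjusted p = 0.0032, and 0.0843 with an estimated correlation; list median -0.48, and 0.36 with housekeeping scaling). Housekeeping scaling shifted the median of all genes by 0.84 as well, and the list still passed with it as lower than other genes. With ribosomal protein scaling the list did not pass (camera adjusted p = 0.12). The mitochondrial Idh2, Idh3a and Sdha had log2 changes of -2.44, -1.21 and -0.11 with adjusted p = 0.273, 0.368 and 0.852. Oxidative phosphorylation genes fell in 5 of 72 cases, and in none with housekeeping scaling (camera adjusted p = 0.000108, and 0.0207 with an estimated correlation), but with housekeeping scaling the list did not pass (adjusted p = 0.407) and its median went from -0.42 to 0.42, and with ribosomal protein scaling its direction turned (adjusted p = 0.289). Over the other alternatives its adjusted p was 0.0207 or lower. Glycolysis genes rose in 8 of 25 cases (14 with housekeeping scaling; 12 rose and 3 fell adjusted over the list alone; camera adjusted p = 2.85e-05, and 0.0173 with an estimated correlation), with log2 changes of 2.88 for the lactate exporter Slc16a3 and 1.73 for Hk3. HIF-1 targets rose in 6 of 19 cases, 13 with housekeeping scaling (camera adjusted p = 7.24e-09, and 0.0103 with an estimated correlation). Hif1a itself is in that list and rose by 1.79 (SE 0.22, limma adjusted p = 0.00446). The list shares Slc2a1, Pdk1, Ldha, Pgk1 and Slc16a3 with the glycolysis list, so their results are not independent. NRF2 and glutathione genes rose in 7 of 19 cases and fell in 1 (adjusted p = 4.54e-05, and 0.0207 with an estimated correlation), with Gclm at a log2 change of 2.13.

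Ass1, argininosuccinate synthase, was at 7.34 ± 0.19 (n = 3) with LPS plus IFNg against 0.06 ± 0.08 (n = 2), adjusted p = 0.0159, while Asl had a log2 change of -0.33 (adjusted p = 0.874). Arg1 rose here too, by 4.40 (SE 0.48, adjusted p = 0.00287). So did Slc7a2, by 5.50, which did not pass between the stimuli in limma (log2 difference 0.08, adjusted p = 0.86). In the arginine list 4 of 16 rose, its median was -0.06 (-0.10 without the member listed at 0 in a whole group) and its mean 1.59 (the test's direction was up), and its call (camera adjusted p = 0.0434) was lost with an estimated correlation (adjusted p = 0.269) and without 5 of the 8 libraries in turn: unstimulated replicate 1 (0.0748), IL4 replicates 2 and 3 (0.128 and 0.0869), and LPS plus IFNg replicates 1 and 3 (0.0643 and 0.113). Gfpt1, the entry enzyme of UDP-GlcNAc synthesis, rose by 2.34 (SE 0.28, adjusted p = 0.00368), and 3 of the 39 members of its list fell (4 higher and 3 lower with housekeeping scaling). Glutamine synthetase Glul fell by 2.33 (adjusted p = 0.00746; lost without either unstimulated library, up to 0.0737), and the cystine transporter Slc7a11 rose by 5.12 (adjusted p = 0.00215). Among fatty acid genes Acsl1 rose by 5.25 (adjusted p = 0.00295).

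Cell cycle genes were lower with LPS plus IFNg: 23 of 41 fell and none rose (33 adjusted over the list alone; camera adjusted p = 1.32e-20, and 0.00278 with an estimated correlation). Ccna2, at 7.73 ± 0.01 (n = 2) without stimulus, was listed at 0 in all 3 LPS plus IFNg libraries, as was Ube2c. Rrm1 did not pass (log2 change -4.85, adjusted p = 0.0883). Ribosomal protein genes fell in 53 of 72 cases, with a median log2 change of -1.64 (66 adjusted over the list alone; camera adjusted p = 3.69e-39, and 0.0117 with an estimated correlation); 17 fell with housekeeping scaling, and ribosomal protein scaling, which equalises their mean, left 1 lower and 3 higher. Neutrophil and granulocyte precursor markers fell in 4 of 12 cases (7 adjusted over the list alone; camera adjusted p = 1.19e-06, and 0.021 with an estimated correlation), with log2 changes of -3.47 for S100a9 and -3.22 for Mmp8, beside the fall of the cell cycle genes. Cholesterol synthesis genes fell in 2 of 22 cases (camera adjusted p = 0.00868, 0.0596 with an estimated correlation, and 0.0919 without unstimulated replicate 2; list median -0.998, and -0.16 with housekeeping scaling, which left 1 higher and none lower). Housekeeping scaling shifted the median of all genes by 0.84, and the cholesterol list still passed with it as lower than other genes. Lysosome (camera adjusted p = 0.0124) and macrophage identity genes (camera adjusted p = 0.0461) passed as lists but not with an estimated correlation (adjusted p = 0.189 and 0.229). Both turned direction with ribosomal protein scaling, and their medians of -0.40 and -0.53 went to 0.44 and 0.31 with housekeeping scaling. The lysosome call was also lost without unstimulated replicate 1 (0.130) and LPS plus IFNg replicate 2 (0.0674), and that of macrophage identity without any 1 library except IL4 replicate 2 and LPS plus IFNg replicate 1 (up to 0.163). The alternative activation list did not pass (5 rose and 7 fell of 31, adjusted p = 0.197). It passed as lower than other genes with housekeeping scaling (0.0144), though 7 rose and 7 fell and its median went from -0.31 to 0.53, and with ribosomal protein scaling (0.00253). Among its members Mrc1 fell by 4.30 and Chi3l3 by 4.83. List tests of the pentose phosphate, fatty acid, glutamine uptake, N-glycosylation, LXR, immediate early, dendritic, mast cell, lymphocyte, erythroid, fibroblast and osteoclast lists did not pass (adjusted p from 0.091 for N-glycosylation to 0.916). The immediate early list passed with housekeeping (0.0498) and ribosomal protein scaling (0.0308). Median and mean differed in sign in the pentose phosphate, immediate early and mast cell lists, and in the dendritic list the test went up while both were below 0.

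In limma, 506 genes were higher and 579 lower with LPS plus IFNg than without stimulus. The largest rises included Clic5, Slfn4 and Gbp4, and the largest falls Nptx1, Cenpf, Mamdc2, Fat3 and Kif2c. With the replicate number as a block there were 255 and 256, without LPS plus IFNg replicate 2 there were 332 and 369, and without unstimulated replicate 2 there were 383 lower. Housekeeping scaling shifted the median of all genes by 0.84 and gave 1483 higher and 239 lower; ribosomal protein scaling shifted it by 1.55 and gave 5793 and 173. Changes are therefore relative to the authors' normalisation, which keeps that median near 0. Of the 81 called genes that the naming rule takes, 45 stayed past the threshold whichever library was left out; Gbp4 and Ass1 did not without any 1 of the unstimulated or LPS plus IFNg libraries (adjusted p up to 0.122 and 0.118), nor H2-T22 without unstimulated replicate 1 or LPS plus IFNg replicates 2 or 3 (up to 0.107), nor H2-Q7 and S100a9 without unstimulated replicate 1 (0.0571 and 0.0519).

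**Figure D2:**
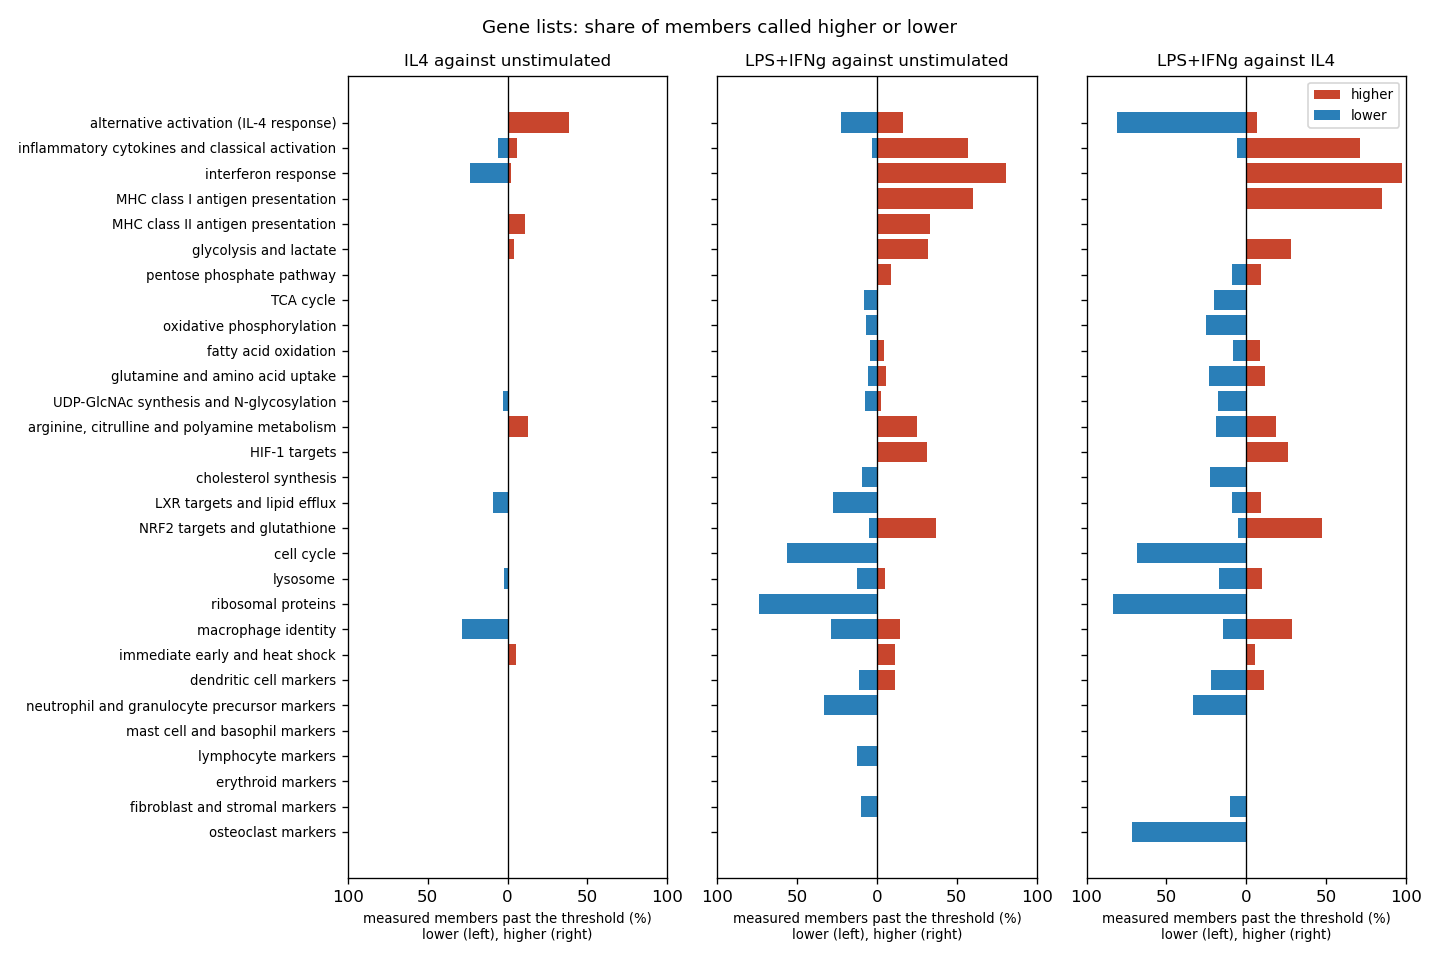
Share of measured members of each of the 29 gene lists that passed the threshold in limma, in percent (horizontal axis; lower to the left, higher to the right), for the 3 comparisons. Interferon response genes reach 34 of 42 higher against no stimulus and 41 of 42 against IL4; the 53 and 60 falls of ribosomal protein genes come to 17 and 41 with housekeeping scaling.

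The direct comparison of LPS plus IFNg with IL4 tests where the activation states differ. Of 31 alternative activation genes, 25 were lower with LPS plus IFNg and 2 higher (25 and 2 adjusted over the list alone; camera adjusted p = 6.37e-17, and 0.00277 with an estimated correlation). Retnla differed by -11.59 (SE 0.58, adjusted p = 0.000109), Chi3l3 by -10.39 (SE 0.53) and Mrc1 by -5.66 (SE 0.28, adjusted p = 0.000105). Irf4, a transcription factor, was listed at 0 in all 3 LPS plus IFNg libraries and at 7.74 ± 0.28 (n = 3) with IL4. Interferon response genes were higher in 41 of 42 cases (adjusted p = 2.92e-45, and 0.00409 with an estimated correlation); Trim21 was the member that did not pass (log2 difference 3.94, adjusted p = 0.0705). Inflammatory genes were higher in 25 of 35 cases and lower in 2 (adjusted p = 1.64e-16, and 0.0138 with an estimated correlation), with Ccl5 at 12.15 ± 0.45 against 1.92 ± 0.57 (n = 3 each). MHC class I genes were higher in 17 of 20 cases (adjusted p = 2.26e-17, and 0.00728 with an estimated correlation). For MHC class II genes no member passed and the list's adjusted p was 0.865.

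Oxidative phosphorylation genes were lower with LPS plus IFNg than with IL4 in 18 of 72 cases (24 adjusted over the list alone; camera adjusted p = 9.95e-12, and 0.00442 with an estimated correlation), with differences of -1.73 for Atp5g3 and -1.64 for Uqcr11. With ribosomal protein scaling that list did not pass (adjusted p = 0.216, against 0.00442 or lower over the other alternatives). Genes of the TCA cycle list were lower in 5 of 25 cases (adjusted p = 4.34e-05, and 0.0339 with an estimated correlation): Sdha differed by -1.14 (SE 0.18, adjusted p = 0.00692) and Idh1 by -1.80 (SE 0.28, adjusted p = 0.00675). Sdha did not pass with housekeeping scaling (-0.52) and turned with ribosomal protein scaling (0.37), which also took Idh1 to -0.30, not past the threshold. With housekeeping scaling 2 TCA cycle and 4 oxidative phosphorylation genes were lower, and the list medians of -0.83 and -0.72 went to -0.22 and -0.11. That scaling shifted the median of all genes by 0.61 as well, and both lists still passed as lower than other genes. Irg1 was higher by 9.30 (SE 0.48, adjusted p = 0.000111). Genes of UDP-GlcNAc synthesis and N-glycosylation were lower in 7 of 39 cases (camera adjusted p = 0.00752, and 0.044 with an estimated correlation). With ribosomal protein scaling that adjusted p was 0.238, the highest over the alternatives. Housekeeping scaling gave 3 higher and 3 lower and took the list median from -0.54 to 0.07. It shifted the median of all genes by 0.61 as well, and the list still passed with it as lower than other genes. Among the lower genes was Man1a, a mannosidase, at -2.63. Gfpt1 went the other way without passing (0.91, limma adjusted p = 0.0538), and St3gal6 did not pass (adjusted p = 0.296). The glutamine transporter Slc1a5 was lower, at 3.65 ± 1.17 against 7.50 ± 0.50 (n = 3 each, adjusted p = 0.00827), in a list where 4 of 17 were lower and 2 higher and the test did not pass (adjusted p = 0.197); with housekeeping scaling 3 were higher and 1 lower. Arg1 differed by -5.93 (SE 0.43) and Ass1 by 4.75 (SE 1.16, adjusted p = 0.0374). Glycolysis genes were higher in 7 of 25 cases (adjusted p = 0.0133, and 0.06 with an estimated correlation), with Pfkfb3 at a difference of 4.04 (SE 0.66), while Hk2 and Ldha differed by -0.10 and 0.11 with adjusted p = 0.823 and 0.689.

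**Figure D3:**
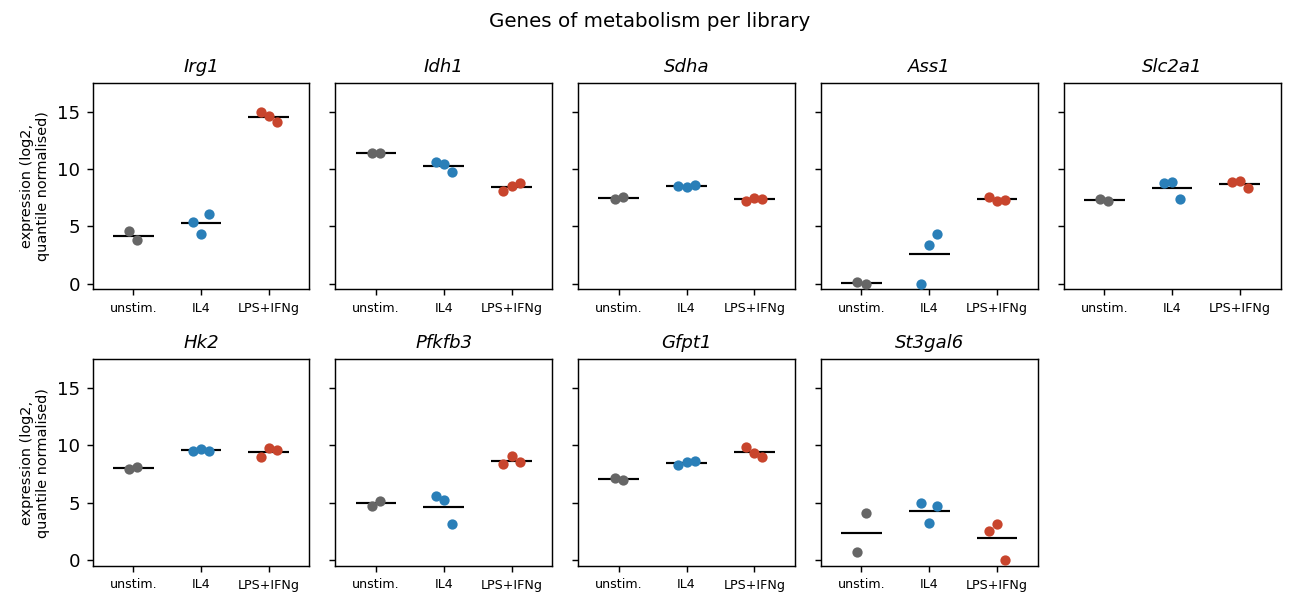
Quantile-normalised log2 expression (vertical axis) of 9 genes of metabolism in each library of the 3 groups (horizontal axis); points are libraries and bars are group means. Irg1 averages 14.55 with LPS plus IFNg, and Idh1 averages 11.39, 10.25 and 8.45 without stimulus, with IL4 and with LPS plus IFNg.

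Cell cycle genes were lower with LPS plus IFNg than with IL4 in 28 of 41 cases (adjusted p = 4.12e-19, and 0.00277 with an estimated correlation), neutrophil precursor markers in 4 of 12 (adjusted p = 0.000193, and 0.044 with an estimated correlation) and cholesterol synthesis genes in 5 of 22 (adjusted p = 0.000554, and 0.0284 with an estimated correlation). With housekeeping scaling 2 cholesterol genes were lower and 1 higher, and the list median went from -1.29 to -0.67. The cholesterol list still passed with that scaling as lower than other genes. Ribosomal protein genes were lower in 60 of 72 cases (adjusted p = 1.54e-34, and 0.0138 with an estimated correlation), in 41 with housekeeping scaling, and with ribosomal protein scaling, which equalises their mean, in 3 with 4 higher. HIF-1 targets were higher in 5 of 19 cases, 10 with housekeeping scaling (adjusted p = 2.86e-05, and 0.0154 with an estimated correlation) and NRF2 genes in 9 with 1 lower (adjusted p = 6.7e-06, and 0.0141 with an estimated correlation). Osteoclast markers were lower in 5 of 7 cases (camera adjusted p = 0.0137), a list call lost with an estimated correlation (adjusted p = 0.0889). Of these members, Ctsk, Tm7sf4, Itgb3 and 4833422F24Rik did not pass in limma without IL4 replicate 1. The lysosome list did not pass (adjusted p = 0.353) and its direction turned with ribosomal protein scaling (0.024), nor did those of macrophage identity, LXR, pentose phosphate, fatty acid, arginine, immediate early, dendritic, mast cell, lymphocyte, erythroid and fibroblast genes pass (adjusted p up to 0.982). Median and mean differed in sign in the macrophage identity, pentose phosphate and arginine lists, and in the lymphocyte list the test went up while both were below 0. The macrophage identity list passed as higher with housekeeping (0.0243) and ribosomal protein scaling (0.000192), and the dendritic list passed without the lowest 0.25 of genes by mean (0.0179) and with ribosomal protein scaling (0.0152). In limma 804 genes were higher and 948 lower. Groups did not overlap in 27.1% of all tested genes, against 10% by chance, and in all 1752 called, as a low p nearly requires. Housekeeping scaling shifted the median of all genes by 0.61 and gave 1640 higher and 477 lower; ribosomal protein scaling shifted it by 1.501 and gave 6816 and 283. Of 83 called genes that the rule takes, 65 stayed past the threshold whichever library was left out. Ass1 did not without either unstimulated library, IL4 replicate 2 or any 1 LPS plus IFNg library (adjusted p up to 0.117).

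Genes past the threshold in both comparisons with no stimulus were then counted. 75 changed in the same direction, 24 higher and 51 lower in both, and 26 in opposite directions, 22 of them lower with IL4 and higher with LPS plus IFNg. Some of the 75 had a log2 difference of exactly 0 between the stimuli, among them Nlrc3, Sncaip and Gpr34, which fell, and Vmn1r175, which rose. Nlrc3 was listed at 0 in every IL4 library, so such shared changes may rest on listed zeros in both stimulated groups. In that case the rise of Vmn1r175 (log2 change 1.65 with either stimulus) would rest on unstimulated values under 0, and not on a gain of reads. Among the opposite responses were Ifit3, Cxcl10, Fcgr1 and Ctsh, lower with IL4 and higher with LPS plus IFNg, and Chi3l3, the other way. All 26 also differed between the stimuli in limma (largest adjusted p = 0.000497, for Fcgr1). That difference is the sum of the sizes of the 2 opposite changes, so its passing adds nothing beyond the choice of these genes. Of their IL4 calls, Chi3l3 was lost without unstimulated replicate 2 (adjusted p = 0.0566), and Cxcl10, Ctsh and Fcgr1 were lost without an unstimulated library and without each LPS plus IFNg library (up to 0.0861, 0.0682 and 0.199). Independent lists of these sizes would share 7.19 and 6.99 genes, and simulated unchanged groups against the same controls shared 0 in either direction on average over 50 simulations; as almost no unchanged gene is called, that count does not measure what the shared controls add. The covariance of the log2 changes was 0.164 over 7283 genes, against 0.181 in the simulations, and the correlation across genes was 0.145 against 0.601. With unstimulated replicate 1 as the control for IL4 and replicate 2 for LPS plus IFNg, 68 genes changed in the same and 22 in opposite directions (9.92 and 9.56 for independent lists), and 74 and 30 the other way round (11.18 and 10.97). The covariance was then 0.0289 and 0.0501. A lone control's own spread is not measured and is assumed to equal that of the other groups, so part of the excess over independent lists in the full fit may still come from the shared controls. Same-direction counts were 307 without unstimulated replicate 1 and 237 without unstimulated replicate 2. The opposite count was 8 without unstimulated replicate 2, 16 without IL4 replicate 1, and 11, 8 and 9 without LPS plus IFNg replicates 1, 2 and 3.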

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

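The alternatives were fixed before the data were examined, except the filter at a mean of 5, the setting of values below 0 to 0 and the fits with 1 control for each stimulus, which were chosen after. Over all alternatives, 94.8% of 1371 list tests and 88.4% of 6046 values of named genes kept their direction and side of the threshold, and 70.8% of 120 counts of genes and 63.2% of 38 counts of shared or opposite genes stayed within 1.5 times. For IL4 against no stimulus the main counts were 70 higher and 108 lower. Fitting only the 2 groups gave 16 and 54, leaving out the lowest 0.25 of genes by mean 110 higher, housekeeping scaling 107 and 71, an adjusted p of 0.01 8 and 2, and a mean of at least 5 113 higher. For LPS plus IFNg against no stimulus (506 and 579), housekeeping scaling gave 1483 and 239, ribosomal protein scaling 5793 and 173, and an adjusted p of 0.01 221 and 217. For LPS plus IFNg against IL4 (804 and 948) these gave 1640 and 477, 6816 and 283, and 427 and 379. Genes shared in direction (75) numbered 5 at an adjusted p of 0.01. Opposite genes (26) numbered 49 without those low genes, 44 with ribosomal protein scaling, 1 at an adjusted p of 0.01 and 59 with a mean of at least 5. The stricter threshold and the shift of every gene by a scaling act by construction; for the others the cause was not tested.

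Leaving out a library gave ranges of 40 to 135 and 63 to 277 for IL4, 332 to 531 and 369 to 581 for LPS plus IFNg, 561 to 752 and 633 to 782 between the stimuli, 52 to 307 for shared and 8 to 22 for opposite genes. Where a control was left out, the lone control is assumed to vary like the other groups.

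Ribosomal protein scaling reversed 4 list directions: oxidative phosphorylation (adjusted p = 0.289), lysosome (0.345) and macrophage identity (0.365) against no stimulus, and lysosome against IL4 (0.024). It also turned the log2 changes of Cox4i1 to 0.31, Ndufa4 to 0.35, Etfa to 0.0799, Plin2 to 0.39, Sdha to 1.45 and Uap1 to 1.27 against no stimulus, and of Etfa to 0.00467, Sdha to 0.37, Hk2 to 1.40, Glul to 0.20, Got1 to 1.31 and Got2 to 1.22 against IL4. The shift of all genes by that scaling accounts for the turned log2 changes of these genes by construction. The list test sets members against all other genes, which that scaling shifts by the same log2 amount. The reversed list directions thus do not follow from the shift alone, and their cause was not tested.

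Replicate numbers are shared between groups in the labels. Deviations from the group means correlated at -0.0791 to 0.0718 in the 7 same-numbered pairs and at -0.0718 to 0.0814 in the 14 others. Deviations within a group add up to 0, and those of the unstimulated libraries mirror each other. These values therefore cannot tell whether same-numbered samples share an animal, a day or a batch. With the number as a block, counts were 7 and 1 for IL4, 255 and 256 for LPS plus IFNg against no stimulus, with 4 shared and 1 opposite gene; between the stimuli they stayed within 1.5 times. Not every sample correlated best with its own number.

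Depth is not given with quantile-normalised values and may be lower in the stimulated libraries. Means under 5 in both groups compared were found for 34, 113 and 170 called genes. At a mean of at least 5, 129 of 132, 807 of 824 and 1318 of 1346 called genes still tested were called again.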

Other observations

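The scaling, shared-value and IL4 low-level tests below were set after related results had been seen, as were the families of gene symbols; the tests on matched levels, transcript length, barcodes and other splits were set before.

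Chemokines of the CC family, grouped by symbol, were higher with IL4: 6 of 15 rose and none fell, and with LPS plus IFNg 6 rose and 2 fell. With IL4, Ccl17 and Ccl22, which attract T cells, were at 4.81 ± 0.41 and 6.61 ± 0.58 (SD, n = 3) and had log2 changes of 4.70 and 6.55, and Ccl2 and Ccl7, which attract monocytes, of 3.28 and 4.55. With LPS plus IFNg, Ccl2 and Ccl7 rose too (3.64 and 3.33), and Ccl5 had a log2 change of 8.84 and Ccl6 of -1.77. Between the stimuli, Ccl2 did not pass in limma (adjusted p = 0.567). Ccl7 did, lower with LPS plus IFNg than with IL4 (log2 difference -1.22, adjusted p = 0.0442). Ccl17 and Ccl22 also belong to the alternative activation list and Ccl2, Ccl5 and Ccl7 to the inflammatory list; apart from Ccl5 and Ccl7, these genes were chosen after their values were seen. Among 154 symbol families tested with camera, the CC chemokines passed for IL4 (adjusted p = 2.09e-09) and LPS plus IFNg (adjusted p = 0.0113), but not with an estimated correlation (adjusted p = 0.353 and 0.372).

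Ribosomal protein genes had a median log2 difference of -1.54 between LPS plus IFNg and IL4, and of -0.02 between IL4 and no stimulus. Scaling of the libraries was set against this with equal housekeeping means, which left a median of -0.933 (SE 0.0629), past the bound of -0.5, and argues against a scaling error of that size as the whole cause. Among 10000 random lists of other genes matched on level, the lowest median was -0.571, which argues against a compression of abundant transcripts. Other genes as abundant, with transcripts up to the 90th percentile of the ribosomal protein lengths (1832 nucleotides), numbered 417 and had a median of -0.361. This argues against a loss of transcripts up to that length as the whole cause. A loss limited to the shortest transcripts stays open, as these genes were not matched singly on length. A change with the stimulus itself may account for the pattern and was not tested; a scaling error larger than the housekeeping genes show stays open, as their own mean was lower in all 3 LPS plus IFNg libraries.

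Many genes in a library shared exactly equal low values, as steps of whole read counts would after normalisation. In 7 of 8 libraries the best filled step lay at step 4 or later and held more genes than the lowest step by over 3 Poisson SD; the exception was unstimulated replicate 1, with 100 genes at step 7 against 82 at the lowest. Several reads per cDNA molecule, from PCR, is a candidate explanation that these counts leave open. Reads given the wrong barcode would place genes abundant with LPS plus IFNg on the lowest steps of the IL4 libraries. There, 37 of 880 entries (a gene in a library, so a gene can count up to 3 times) had an LPS plus IFNg mean of at least 8, against 30 of 1494 on the best filled steps, a ratio of 2.09 (95% interval 1.30 to 3.36, too narrow as it treats entries as independent), which includes the bound of 1.5 set beforehand, so this stays open too; no biological explanation was tested.

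Step 10 stood at log2 values of 0.15 and 2.14 in the unstimulated libraries and of 3.28, 3.68 and 3.47 with IL4, so quantile normalisation may create differences at the low end. For genes above 0, an equal step was thus listed higher with IL4. Whether that gives false rises depends on depth, which is not given. A lower depth with IL4, which its higher number of zeros may mean, could instead turn low genes into falls to 0. Of the 108 genes lower with IL4, 24 had means under 5 in both groups, or 22.2% (exact 95% interval 14.8 to 31.2), against 10 of the 70 higher. The interval lies under the 50% bound set for most of these falls and spans the 20% bound under which the explanation would be excluded. This share cannot decide, as it misses falls from a mean over 5 to 0. Of the 108 genes, 26 were listed at 0 in every IL4 library. The explanation stays open, as does a response to IL4, untested.

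Of the 10 splits of the 6 stimulated libraries into 3 and 3, the real one called 1752 genes and the highest of the others 1. With 10 splits the share that call as many cannot be under 0.1, too few to tell.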
